A study of Mus musculus with 2 samples.

How the data were processed

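Total RNA from adrenal gland tissue of 2 female mice of the F1 cross between C57BL/6J and CAST/EiJ (strain B6CASTF1/J), aged 18 to 20 months, was sequenced. Per the labels' protocols, each library was made from 300 ng of RNA with a kit that keeps the strand of the transcript, after reduction of ribosomal RNA, with ERCC spike-ins added, which are synthetic RNAs of known sequence. The libraries form 1 group with 1 library per animal. They are called animal 1 and animal 2 after the biological replicate numbers in the labels. One label field of animal 2 repeats the animal and library names of animal 1, while its other fields name a different female and a separate tissue sample. The labels give both samples the same donor identifier, although the replicate numbers, the names of the females and the tissue samples differ. The series holds no second group, age, sex or treatment, so no comparison between groups was made.

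For each library a gene table, a transcript table and a second transcript table were used. Per the file headers, the gene table and the transcript table hold expected counts (estimated reads or fragments per feature, which need not be whole) and TPM (transcript abundance scaled to a fixed total over all entries, spike-ins included). Their column names are those that the program RSEM writes, and the gene table also holds the deposited lower and upper bound of an interval of each TPM, whose level is not given in the sources used here and was taken as 95%. The deposited description of the files says that these tables were derived from an alignment to the transcriptome, with the mouse assembly mm10 and GENCODE annotation M21. The second transcript table holds estimated counts and TPM deposited by the authors. Its column names are those that the program kallisto writes, and the description says that it was derived directly from a pair of read files and an index. The names and versions of the programs are not given in the sources used here. The deposited interval bounds cover a posterior estimate of TPM and not the printed TPM itself. Among 13570 genes with a mean expected count of at least 50, the printed TPM lay inside its own interval for 96.8% in animal 1 and 96.3% in animal 2.

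All 55536 gene identifiers of the gene table were found in GENCODE M21 on GRCm38, the assembly also called mm10, from which symbols, biotypes and coordinates were taken. The table also lists 96 spike-ins and 26248 entries named only by a number, which were left out of all results. Expected counts summed to 35769717 in animal 1 and 35135703 in animal 2, and the estimated counts of the second transcript table to 34601631 and 34894349. A count of 0 allows up to 3 counts, or 0.0839 and 0.0854 after scaling to CPM in animals 1 and 2. Binomial intervals (Wilson, 95%) and this limit cover counting error only, since reads without molecular identifiers are not independent molecules.

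The remaining values were computed from the deposited tables. Expected counts were rounded to whole numbers and scaled with TMM in edgeR 4.0.16 (R 4.3.3). The log2 ratio of a gene is that of animal 2 over animal 1, with 0.5 added to each count, so positive values are higher in animal 2. A gene was called detected at a TPM of at least 1 in both libraries. The spread between the animals is the square root of the edgeR common dispersion of an intercept-only model over genes with a mean count of at least 10. Differences between the library preparations are part of it, since 1 library per animal cannot separate them from the animals. A gene was counted as at least 2-fold apart if its scaled ratio reached 2 either way, its mean expected count was at least 50 and its deposited TPM intervals did not overlap. With 1 library per animal this rule gives no p-value. For 28 gene lists fixed before the data were examined, the median log2 ratio of members with a mean count of at least 10 was placed among 10000 random lists of equal size, matched on mean expression in 20 bins. A list was called outside the range if its median lay below the 2.5 or above the 97.5 percentile, and lists with fewer than 3 measured members have values only. These percentiles describe the 2 libraries and are not a test of a condition. Agreement of the 2 quantifications was taken as log2((TPM + 1)/(TPM + 1)) of the second over the first table. Means are given with the SD over the 2 animals, on which an exact sign-flip test could not go below a two-sided p of 0.5, so none was run.

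The genes named were set by a rule fixed together with the lists. It takes the 10 genes with the highest mean TPM, the whole steroidogenesis core list, up to 4 members of every other list with the highest mean TPM, and undetected members (TPM under 0.1 in both libraries) of lists of 12 or fewer. It also takes the genes of 10 fixed ratios, the 10 genes furthest apart in each direction under the 2-fold rule without predicted genes and pseudogenes, and the 5 genes furthest apart between the 2 quantifications in each direction. Some genes that this rule takes, and 1 of the ratios, are not reported here. Other genes are named only as members of a fixed list, or with the statement that they were chosen after their values were seen.

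A chi-square comparison of the counts with a shared proportion per gene gave a mean of 62.4 per degree of freedom over 17024 genes, against a mean of 1 for 2 draws from a single library. The median gene had 4.76. The tables therefore do not hold 1 library listed 2 times, but this does not show whether 2 animals were sampled. The scripts were tested on simulated counts for 25998 genes with the means and depths of these libraries. With a simulated coefficient of variation of 0.2 and no changed gene, 0.199 was recovered. With 200 genes changed 4-fold, 0.227 was recovered, so genes far apart raise this estimate. Among these 200 genes, 95.5% passed the 2-fold rule without its interval requirement, and so did 2.10% of 13344 unchanged genes. Of 200 unshifted lists of 12 genes, 3% fell outside the central range, and of 50 lists shifted by 0.5 on the log2 scale, 94% did. The simulated genes varied independently, whereas members of a real list can vary together. These rates therefore check the scripts and do not apply to the fixed lists.

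The alternatives tried were median-of-ratios size factors from DESeq2 1.42.0, spike-in totals or deposited TPM in place of TMM, other thresholds, pseudocounts and filters, DESeq2 dispersions, the second quantification, protein-coding genes only, a correction for transcript length and GC content, and each animal alone where a value from a single library exists. Genes that share reads with near-identical copies (Rn7s1 and Rn7s2, Rnu3a, mitochondrial genes and their nuclear pseudogenes, Hba-a1 and Hba-a2, Hspa1a and Hspa1b, immunoglobulin genes) are uncertain as single genes, as are the symbols Nnt and Rmrp, each of which has 2 gene identifiers, of which the one with more counts was used. Reads of the CAST/EiJ allele are compared with a C57BL/6J reference, which can lower the counts of genes rich in differences, such as the H2 genes, in both animals. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.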

Results

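Gene expression in the whole adrenal gland was measured by total RNA-seq in 2 aged female mice of an F1 cross between C57BL/6J and CAST/EiJ, with 1 library per animal and total expected counts of 35769717 in animal 1 and 35135703 in animal 2. The adrenal gland consists of a cortex, which makes steroid hormones, and a medulla, whose chromaffin cells make catecholamines. At a TPM of at least 1 in both libraries, 12552 genes were detected, of which 11552 were protein-coding. Each library alone had 13064 and 12982 genes at this level. Across genes with a TPM of at least 1 in either library, log2(TPM + 1) correlated between the animals with a Pearson r of 0.967 and a Spearman rho of 0.965, where genes are not independent replicates. The spread between the animals beyond counting error, as a coefficient of variation, was 0.242 over 17024 genes, but DESeq2's gene-wise median gave 0.0862. Genes far apart raise the first estimate. On data simulated with 0.2, it gave 0.199 with no gene changed and 0.227 with 200 genes changed 4-fold. With 1 library per animal, the spread also includes any difference in handling or library preparation.

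The steroidogenic genes of the cortex ranged in mean TPM from 3.71 for Nr0b1 to 4491 for Hsd3b1. The 13 genes of the steroidogenesis core list summed to 19530 ± 3657 TPM (SD, n = 2), or 1.95% of all TPM, and all 13 were detected. The sum was 36321 TPM in the second quantification and 64461 TPM when scaled over nuclear protein-coding genes alone. Hsd3b1, the 3-beta-hydroxysteroid dehydrogenase of the cortex (ENSMUSG00000027871.16, mm10 chromosome 3, 98852194 to 98859794), had 4491 ± 887 TPM. Cyp21a1, the 21-hydroxylase (chromosome 17, 34801348 to 34804561), had 4227 ± 932 TPM. Star, which moves cholesterol into mitochondria (chromosome 8, 25806555 to 25815982), had 4179 ± 1690 TPM. Cyp11b1, the last enzyme of corticosterone synthesis (chromosome 15, 74834125 to 74841643), had 2454 ± 238 TPM, and the side-chain cleavage enzyme Cyp11a1 had 2184 ± 212 TPM. Of the electron carriers of the mitochondrial P450 enzymes, Fdx1 had 691 ± 443 TPM and Fdxr 405 ± 0.940 TPM, while Por, which serves the microsomal enzymes, had 105 and 94.9 TPM in animals 1 and 2. The transcription factor Nr5a1 stood at 242 ± 86.7 TPM and its repressive partner Nr0b1 at 3.71 ± 0.240 TPM. The ACTH receptor Mc2r had 111 ± 7.21 TPM and its accessory protein Mrap 260 ± 107 TPM.

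Within this core the animals differed gene by gene. Fdx1 was 2.71-fold, Star 1.86-fold and Mrap 1.77-fold higher in animal 2, whereas Cyp11b2 was 1.25-fold, Cyp11b1 1.19-fold and Cyp11a1 1.18-fold higher in animal 1. The list median of -0.15 on the log2 scale lay inside the central range of random lists, from -0.15 to 0.25, at a percentile of 2.97. Of the 13 genes, Fdx1 passed the rule for genes at least 2-fold apart. Scaling by spike-in totals in place of TMM moved the median over all genes from -0.01 to 0.21, and the core median to 0.07, the opposite sign. With spike-in scaling 10 of the 13 members were higher in animal 2, against 6 with TMM.

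Ratios between genes of the same library do not depend on that scaling. Transcripts of Cyp11b1 exceeded those of aldosterone synthase, Cyp11b2 (chromosome 15, 74851010 to 74856318), by 3.75 ± 0.05 on the log2 scale (SD, n = 2), a 13.1-fold difference in animal 1 and 13.8-fold in animal 2. Hsd3b1 exceeded Hsd3b6, the form of the zona glomerulosa, by 7.66 ± 0.13, and the angiotensin receptor Agtr1a exceeded Agtr1b by 4.91 ± 0.40. Cyp17a1, the 17-alpha-hydroxylase, was near the limit of detection with 4 and 39 expected counts, against 312504 and 248691 for Cyp11b1, so their log2 ratio of 13.24 ± 2.03 rests on few counts. Cyp21a1 exceeded Cyp11b1 by 0.77 ± 0.46, and Mrap exceeded Mc2r, the Mc2r over Mrap ratio being -1.17 ± 0.71. In the medulla, Dbh over Th was -0.79 ± 0.03 and Dbh over Pnmt -0.45 ± 0.32 by TPM. The latter became 0.77 when expected counts were not corrected for transcript length. Without this correction 4 of the other ratios also moved by more than the spread, among them Cyp11b1 over Cyp11b2, Cyp21a1 over Cyp11b1 and Mc2r over Mrap. In the second quantification 3 ratios moved, including Cyp11b1 over Cyp11b2, so the SD over the animals does not cover the choice of processing. The ratio of Akr1c18 to Akr1b7 differed in sign between the animals, -3.30 in animal 1 and 0.44 in animal 2, and its mean is not separable from 0.

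Members of the lists for cholesterol supply, zona glomerulosa and zona fasciculata went both ways between the animals, and the signs of these list medians turned under spike-in scaling. The list for cholesterol uptake, storage and synthesis summed to 2289 ± 332 TPM, with Scarb1, the receptor for high-density lipoprotein, at 728 ± 239, Soat1 at 429 ± 19.9, Dhcr7 at 271 ± 71.8 and Fdps at 111 ± 9.39 TPM. Its median was -0.10, at a percentile of 1.13, with 13 of 22 members higher in animal 1. Under spike-in scaling the median was 0.12, and 15 members were higher in animal 2. The zona glomerulosa list summed to 923 ± 0.863 TPM, with the potassium channel Kcnk3 at 421 ± 17.5 TPM, Cyp11b2 at 183 ± 24.6, Dab2 at 143 ± 8.28 and Agtr1a at 87.2 ± 21.6 TPM. Its median of -0.10 was inside the random range (percentile 10.8), and it was 0.12 with spike-in scaling. The zona fasciculata list summed to 4088 ± 339 TPM, with Akr1b7, an aldo-keto reductase, at 954 ± 270 while the transporter Abcb1b had 262 TPM in animal 1 and 358 in animal 2. Its median was -0.18 (percentile 4.87), also inside the range, and it was 0.04 with spike-in scaling. After a correction for length and GC content it was -0.24 and outside the range (percentile 1.75).

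**Figure D1:**
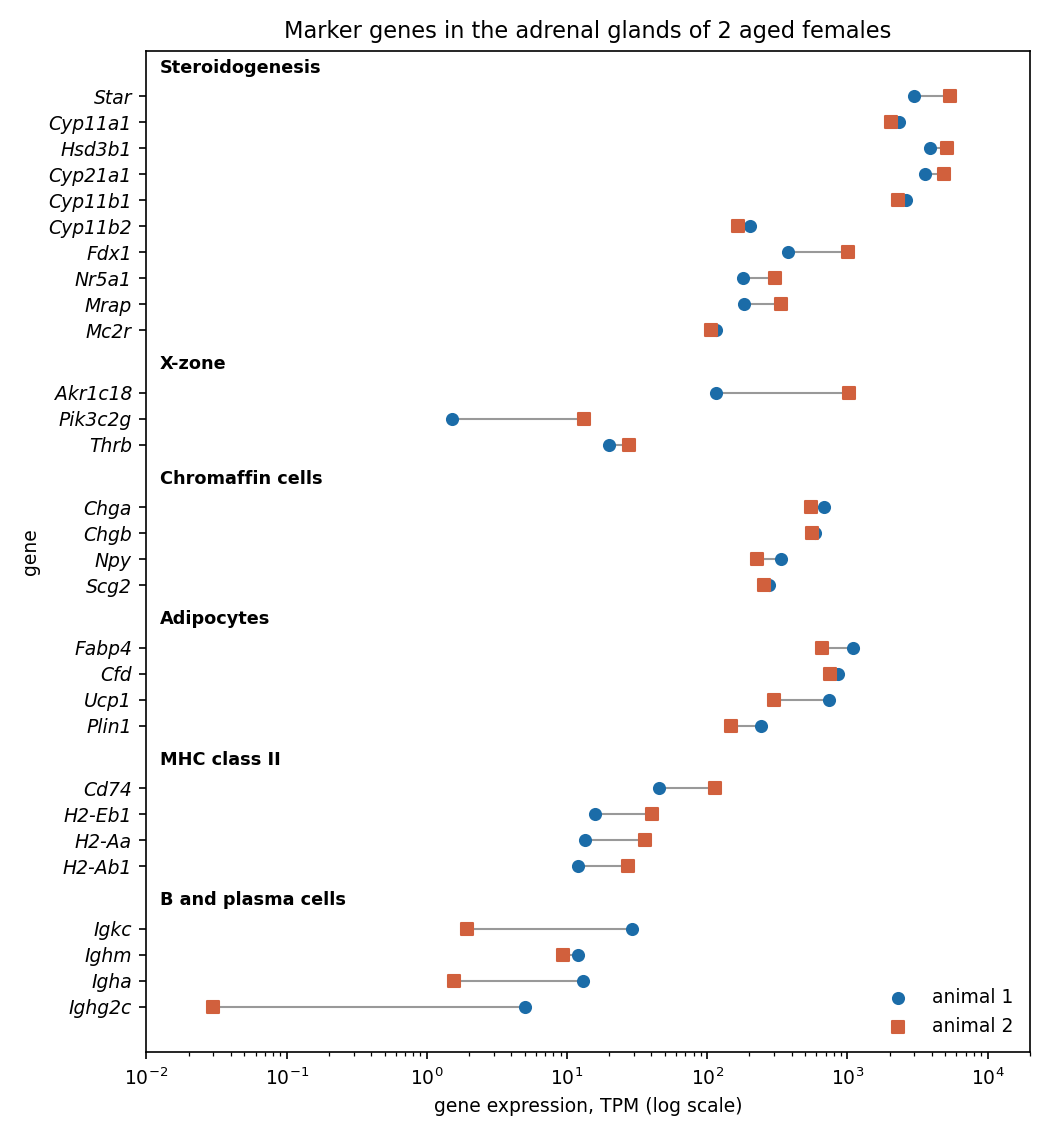
TPM on a log scale of named marker genes in animal 1 (circles) and animal 2 (squares), 1 library each, grouped by fixed gene list, with a grey line joining the 2 values of a gene. Star stood at 2984 and 5374 TPM, while Akr1c18 stood at 116 and 1034 TPM and Igkc at 28.9 and 1.95 TPM.

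Genes of the X-zone, an inner cortical layer of young and female mice, had the highest median of the 26 fixed lists. Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase that marks this zone (ENSMUSG00000021214.14, chromosome 13, 4132615 to 4150654), had 116 TPM in animal 1 and 1034 TPM in animal 2, an 8.58-fold difference from 4959 and 40158 expected counts. Pik3c2g, another marker of the zone (chromosome 6, 139587221 to 139969284), had 1.52 and 13.2 TPM, a 10.4-fold difference. Thrb, a thyroid hormone receptor with wider expression, had 19.8 and 27.8 TPM. The list median of 3.10 lay above all 10000 random lists, and it was 3.32 with spike-in scaling.

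Chromaffin cell genes were slightly lower in animal 2. All 16 members had a lower scaled count in animal 2, 11 of them with TPM intervals that did not overlap, and the median of -0.32 lay below all random lists. With spike-in scaling the median was -0.10 and 5 of the 16 were higher in animal 2. The granins Chga and Chgb had 612 ± 91.8 and 576 ± 22.0 TPM, Npy 280 ± 77.5 TPM and Scg2 264 ± 14.3 TPM. Among the catecholamine enzymes, Th had 232 and 165 TPM, Dbh 136 and 94.0 TPM, and Pnmt, which makes adrenaline, 159 and 150 TPM. No member passed the 2-fold rule.

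Several lists of markers of other cell types also differed between the gland samples, which may hold tissue from around the gland. The list of white and brown adipocytes summed to 3514 TPM in animal 1 and 2255 TPM in animal 2, and all 10 members were higher in animal 1 under TMM and under spike-in scaling. Its median was -0.63, below all random lists. Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), had 743 and 298 TPM, a 2.58-fold difference, and Fabp4 had 1105 and 659 TPM. Cfd had 859 and 753 TPM and Plin1 240 and 148 TPM. The capsule and fibroblast list was also lower in animal 2 (median -0.39, percentile 0.03, 10 of 11 members, or 8 of 11 with spike-in scaling), with Acta2 at 25.2 and 12.5 TPM, Dcn at 54.3 and 50.2, Col1a2 at 18.1 and 15.4 and Nr2f2, the exception, at 29.7 and 37.2 TPM. The glia list had a median of -0.57 (percentile 0.76) at low levels, with S100b at 5.31 and 4.35, Mbp at 4.15 and 2.65 and Erbb3 at 0.80 and 0.77 TPM. The endothelial list was inside the range (median 0.12, percentile 80.7), with Plvap at 57.3 ± 6.83, Egfl7 at 28.6 ± 2.96, Emcn at 26.0 ± 2.39 and Kdr at 19.3 ± 1.47 TPM. Erythroid transcripts were lower in animal 2, with 5 of 5 members and a median of -0.43 (percentile 0.20), Hba-a1 having 746 and 571, Hbb-bs 687 and 529, Hba-a2 511 and 414 and Hbb-bt 101 and 55.9 TPM. Liver transcripts were low, Alb at 11.2 and 3.45, Apoc3 at 3.91 and 2.38, Apoa1 at 1.45 and 0.78 and Ttr at 0.76 and 0.31 TPM, with a list median of -1.08 (percentile 0.11; -1.75 with no percentile at a mean count of at least 100). Kidney markers were almost absent. Slc34a1 had 0.73 and 0.89, Aqp2 0.25 and 0.43 and Lrp2 0.22 and 0.36 TPM, Umod had 5 counts and 1 count, and Slc12a1, Kap, Nphs1 and Slc22a6 were under 0.1 TPM in both animals. The median of the 3 kidney genes measured, 0.39, was inside the range (percentile 86.2).

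Immune transcripts differed in opposite directions. Antigen presentation genes of MHC class II were higher in animal 2, with 7 of 7 members and a median of 1.12, above all random lists. Cd74, the invariant chain, had 45.0 and 114 TPM, H2-Eb1 15.8 and 40.6, H2-Aa 13.4 and 35.8 and H2-Ab1 12.03 and 27.4 TPM, and 4 members passed the 2-fold rule. Genes of B and plasma cells were higher in animal 1, with 10 of 10 measured members and a median of -1.76, below all random lists, although 1 member was higher in animal 2 under spike-in scaling. At a mean count of at least 100, 3 members remained, with a median of -3.11. Igkc, the kappa light chain constant region, had 28.9 and 1.95 TPM, Igha 13.0 and 1.55, Ighm 11.97 and 9.41 and Ighg2c 5.02 and 0.03 TPM. The macrophage list had a median of 0.24 (percentile 98.8) and a mean of -0.25. Lyz2 had 51.9 and 52.2, C1qa 15.3 and 22.6, C1qb 15.4 and 20.9 and C1qc 12.2 and 16.1 TPM, while the list members Trem2 (4.66 and 1.54 TPM) and Gpnmb (2.85 and 0.24 TPM), named after their values were seen, passed the 2-fold rule with higher values in animal 1. T cell genes were near 0, Lck at 0.42 and 0.70, Trbc2 at 0.27 and 0.23, Cd2 at 0.24 and 0.23 and Trac at 0.21 and 0.10 TPM, with Cd8a and Cd8b1 under 0.1. Lck alone reached a mean count of 10, so the list has no percentile. In the second quantification 3 members reached it, with a median of 0.75 inside the range (percentile 87.1). The interferon response list was inside the range (median 0.18, percentile 92.6), with Bst2 at 20.4 ± 1.32, Rsad2 at 3.63 ± 0.113 and Oasl2 at 2.92 ± 0.0778 TPM.

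The lists for handling stress, glucocorticoid response and the circadian clock had medians above 0, with some members of the first and last lower in animal 2 under TMM scaling (under spike-in scaling, of the last only). All 10 members of the glucocorticoid response list were higher under both scalings and had intervals that did not overlap, and the median of 0.57 lay above all random lists. Mt1 had 65.3 and 99.3, Mt2 26.5 and 61.6, Sgk1 26.2 and 48.9 and Tsc22d3 21.5 and 44.8 TPM. In the list of immediate early and handling stress genes 11 of 14 were higher in animal 2 (median 0.62, above all random lists). The inducible chaperones Hspa1b and Hspa1a had 35.6 and 192 TPM and 14.8 and 77.2 TPM, Nr4a1 85.8 and 83.0 and Jun 34.0 and 48.3 TPM. The circadian list had a median of 0.39, at a percentile of 99.99, with 9 of 14 members higher in animal 2. Nr1d1 had 41.1 and 68.1 and Per1 15.2 and 20.1 TPM, whereas Dbp had 35.7 and 29.2 and Tef 16.6 and 14.2 TPM.

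Senescence and ageing genes were inside the range (median -0.05, percentile 49.3; 0.17 with spike-in scaling). Cdkn1a had 25.3 ± 7.02, Trp53 14.9 ± 1.70, Glb1 9.22 ± 0.467 and Cdkn2a 7.68 ± 7.03 TPM, Cdkn2a being the member that passed the 2-fold rule, with 12.7 TPM in animal 1 and 2.71 in animal 2. Il6 was listed at 0 TPM in both. Proliferation genes were low, Cdk1 at 1.10 ± 0.283, Top2a at 0.895 ± 0.120, Mki67 at 0.595 ± 0.120 and Ccnb1 at 0.570 ± 0.240 TPM, and inside the range (median 0.42, percentile 96.4). With ratios of deposited TPM (percentile 97.8) or protein-coding genes only (99.4) this list lay outside it. Antioxidant defence genes had a median of -0.14 (percentile 1.31), which became 0.0774 with spike-in scaling and lay inside the range after the correction for length and GC content (percentile 2.66). Sod1 had 467 ± 23.7, Gpx4 313 ± 22.4, Prdx3 274 ± 45.6 and Gpx1 233 ± 9.35 TPM. Imprinted genes were inside the range (median -0.03, percentile 27.7; 0.19 with spike-in scaling), with Cdkn1c at 304 ± 103, Meg3 at 228 ± 126, Dlk1 at 209.9 ± 19.4 and Rian at 141 ± 21.5 TPM. Mitochondrially encoded messenger RNAs summed to 62974 ± 5571 TPM and were inside the range (median 0.11, percentile 68.5), led by mt-Co1 at 11085 ± 165, mt-Cytb at 7244 ± 1123, mt-Nd1 at 6890 ± 227 and mt-Atp6 at 6436 ± 638 TPM. This order did not hold in the second quantification, where mt-Atp6 had 25591 and 25166 TPM, above mt-Co1 with 22383 and 20771. Of the sex-linked genes, Xist, transcribed from the inactive X chromosome, had 22.2 and 40.7 TPM, while its antisense gene Tsix and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were under 0.1 TPM in both. In the second transcript table Uty had 0.47 and 0.57, Kdm5d 0.18 and 0.25, Tsix 0.15 and 0.21, Eif2s3y 0.15 and 0.01 and Ddx3y 0.12 and 0.03 TPM.

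**Figure D2:**
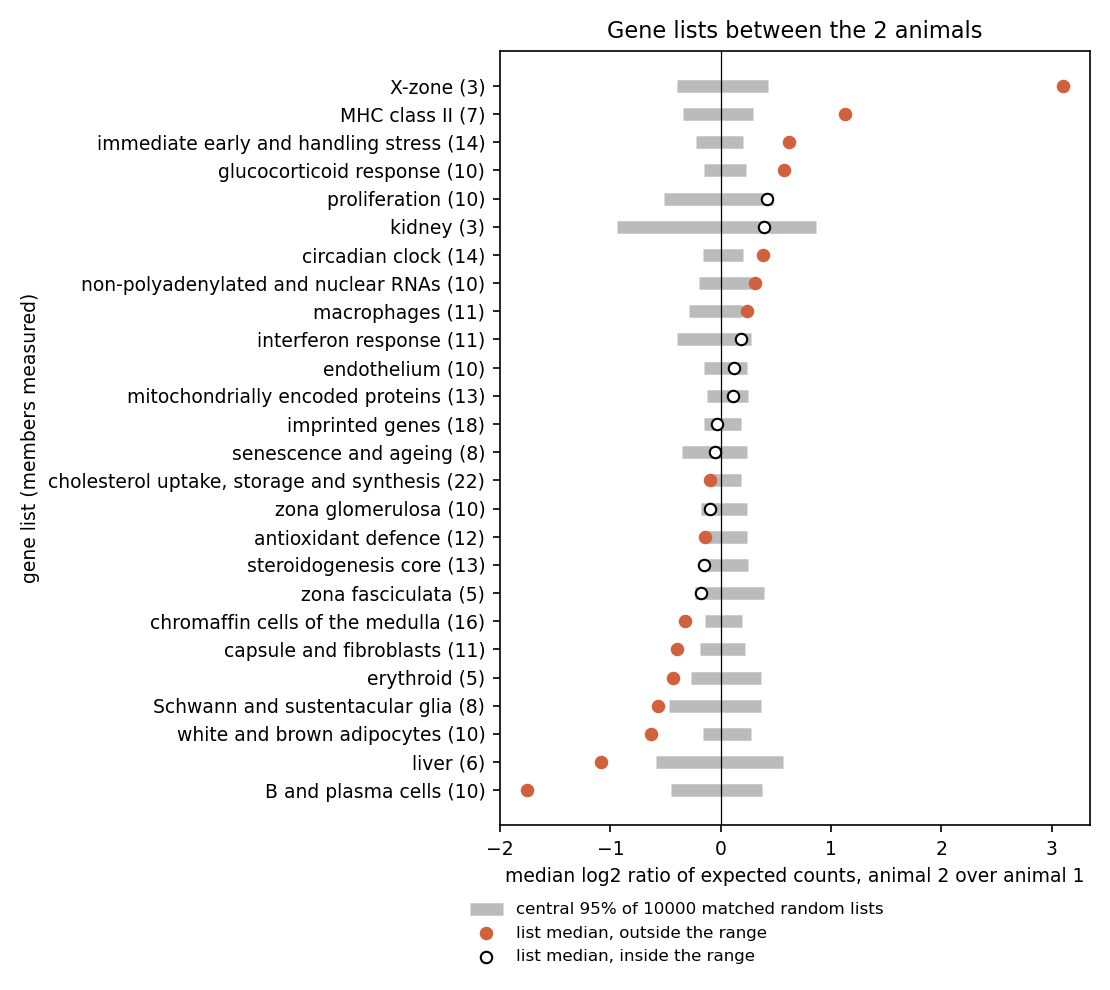
Median log2 ratio of expected counts, animal 2 over animal 1, of the 26 fixed gene lists with at least 3 measured members (points), against the central 95% of 10000 random lists matched on mean expression (grey bars). Filled points, 16 of 26, lie outside their range, from -1.76 for B and plasma cells to 3.10 for the X-zone.

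Of the 26 lists with a percentile, 16 lay outside the central 95% of matched random lists, against 1.30 if all genes varied independently. Members of a list vary together within an animal and some lists share genes, so that number is no measure of chance here. These counts describe the 2 gland samples and not a difference between conditions.

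Among single genes, 471 of 13570 with a mean count of at least 50 were at least 2-fold apart, 237 higher in animal 1 and 234 higher in animal 2. With spike-in scaling the split was 152 and 393. Of the 10 genes furthest apart with higher values in animal 1, most encode proteins of striated muscle. Atp2a1, the calcium pump of fast muscle (ENSMUSG00000030730.12, chromosome 7, 126445858 to 126463108), had 2701 expected counts in animal 1 and 0 in animal 2, at least 849.5-fold higher against the limit of 3 counts per library. The myosin heavy chains Myh2 (6.80 TPM), Myh7 (2.57 TPM) and Myh4 (1.38 TPM) and the muscle creatine kinase Ckm (27.2 TPM) were listed at 0 in animal 2, and Acta1 had 63.2 and 0.08, Tnnt3 28.1 and 0.25, Myh1 14.9 and 0.01 and Ttn 5.98 and 0.01 TPM. The small nucleolar RNA Rnu3a had 190 and 0 TPM. In the other direction stood Otog (0.03 and 0.90 TPM), the transcription factor Fosb (54 and 680 expected counts, 13.2-fold), Pik3c2g, Akr1c18, Ssu2 (0.38 and 3.53 TPM), 2010109I03Rik (0.48 and 4.39 TPM), Fetub (2.96 and 23.6 TPM), Obp2a (2.67 and 20.2 TPM), the growth factor Gdf9 (0.20 and 1.81 TPM) and the phosphatase Acpp (0.43 and 2.90 TPM).

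Non-coding and mitochondrial RNAs took a large part of the libraries. Nuclear protein-coding genes held 64.2% ± 0.157 of expected counts (SD, n = 2) but 30.2% ± 1.13 of TPM, and 60.1% of TPM in the second quantification. Genes of the mitochondrial genome held 16.9% of expected counts in each library (Wilson 95% interval 16.85 to 16.88 in animal 1 and 16.88 to 16.91 in animal 2). Reads that these genes share with nuclear pseudogenes can be counted in either place, which the intervals do not cover. Unprocessed pseudogenes held 2.29% of expected counts on average. The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, had 179870 ± 12761 TPM each, together 36.0% of TPM and 7.59% of counts. The other genes with the highest mean TPM were mt-Rnr1 (52737 ± 7293), mt-Rnr2 (41996 ± 944), Rn7sk (39189 ± 9609), Gm28661 (14369 ± 1104), Gm26917 (13700 ± 1458), mt-Co1, Gm10925 (10742 ± 1559) and Gm28437 (7692 ± 462). The Gm28661, Gm10925 and Gm28437 entries are unprocessed pseudogenes. The list of non-polyadenylated and nuclear RNAs summed to 41.4% of TPM (414156 TPM, against 3147 TPM in the second quantification) and had a median of 0.31 (percentile 98.5), but lay inside the range with ratios of deposited TPM (percentile 90.01). Rpph1, the RNA of ribonuclease P, had 6640.2 ± 363 TPM, and Rny3 was listed at 0. Small nuclear RNAs held 0.280% of counts in animal 1 and 0.155% in animal 2 (Wilson 95% intervals 0.279 to 0.282 and 0.154 to 0.156).

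Spike-ins took 0.886% of counts in animal 1 and 0.730% in animal 2 (Wilson 95% intervals 0.883 to 0.889 and 0.728 to 0.733). Across the 96 spike-ins, log2(count + 1) correlated between the libraries with an r of 0.993, and over the 44 with at least 10 counts in both with 0.998.

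The 2 deposited quantifications of each library differed in scale and for short RNAs. Of 15653 genes with a TPM of at least 1 in either, 2394 were at least 2-fold higher and 420 at least 2-fold lower in the second transcript table, in both libraries. The median gene was 1.72-fold higher there in animal 1 and 1.64-fold in animal 2. After the ratios were centred on their median, a step chosen after the data were seen, 253 genes were higher and 544 lower. Log2(TPM + 1) correlated between the quantifications across genes with an r of 0.850 in animal 1 and 0.865 in animal 2. The genes lowest in the second table were Rn7s1 and Rn7s2 (2.26 and 2.76 TPM in the second table), mt-Atp8 (0 TPM there, against 6295 on average in the first), Rmrp (0 against 4893 TPM) and Rn7sk (2.46 and 21.6 TPM there). The genes highest in it were Gm28439, Gm22567 and Gm47283 (annotated on chromosome Y, 92.8 and 315 TPM there), at 0 TPM in the first table, the histone gene Hist2h2aa1 (2.02 TPM in the first) and Gm12840 (4.62 TPM in the first). Since the 2 quantifications disagree on Gm47283, its values do not show expression from chromosome Y.

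**Figure D3:**
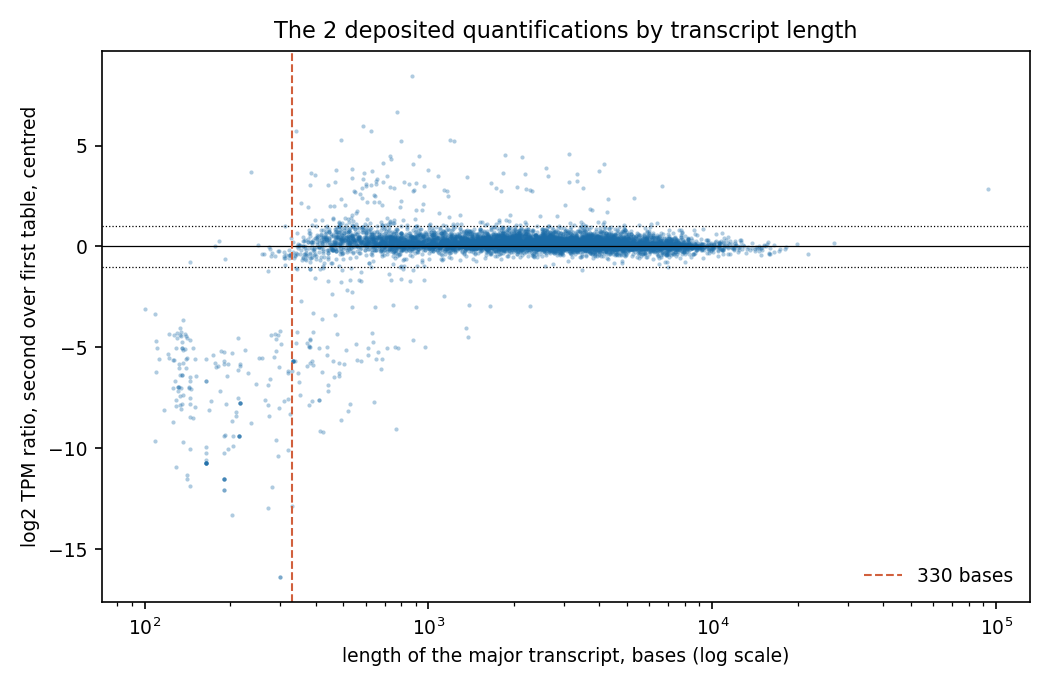
Log2 TPM ratio of the second over the first deposited quantification, averaged over both animals and centred on the median, by length of the major transcript in bases (log scale), for genes with a mean TPM of at least 10 in either. Below 330 bases (dashed line), 165 of 194 genes lie at least 2-fold lower (below the lower dotted line), above it 108 of 8231.

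Major isoforms were compared for 29 genes of the steroidogenesis core and chromaffin lists. Cyp11b1, Cyp11b2, Nr0b1, Mc2r, Chgb, Hand2 and Npy have 1 annotated transcript each. Their share of 100% and their agreement between the quantifications were therefore fixed in advance, and they are included in the values that follow. The most abundant transcript held a median of 96.9% of a gene's TPM, and at least 90% in 17 genes. Both quantifications named the same major transcript for 26 genes. The exceptions were Hsd3b1 (Hsd3b1-201 with 65.7% ± 2.91 in the first quantification, against Hsd3b1-202 in the second), Nr5a1 (Nr5a1-201 with 83.4% ± 1.55, against Nr5a1-202) and Ddc (Ddc-202 with 62.6% ± 7.70, against Ddc-210). Star was divided between 2 annotated transcripts, Star-202 holding 52.8% ± 2.95.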

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

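Entries of the gene tables that are named only by a number and lie outside the gene annotation were used in no comparison. Summed over 26248 such entries, 61 to 259 bases long, there were 3.76 expected counts in animal 1, from 2 entries, and 4.00 in animal 2, from 3 entries. These sums were picked out because they exceed the 3 counts that a count of 0 allows. That limit is meant for a single feature and not for a sum over many, and 26185 of the entries have an effective length of 0, so these few counts do not show a signal. No explanation was tested.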

How the results depend on the processing

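Protein-coding genes only (for genes 2-fold apart and list medians), the correction for length and GC content, the centring of the 2 quantifications and TPM over nuclear protein-coding genes were chosen after seeing the data. Leaving out an animal was not possible for concordance, the coefficient of variation, genes 2-fold apart, list medians and spike-ins, which need both. Replicate concordance (r 0.939 to 0.990) and the number of lists outside their range (15 or 16, of which 14 to 16 were the same lists in the same direction) kept within their tolerance. Median-of-ratios size factors and spike-in totals shift every gene, and so every random list, by the same amount. The percentiles could not change under these scalings, so their count of 16 lists is no check of the result. Of the lists outside their range, those for cholesterol supply (0.12) and antioxidant defence (0.0774) changed sign with spike-in totals, by the shift that this scaling gives every gene. Among lists inside their range, the medians for the steroidogenesis core, zona glomerulosa, zona fasciculata, senescence and imprinted genes changed sign too. No paired analysis was possible because there is 1 group.

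Values of the main results that moved by more than the spread follow. In the second quantification 26 of 28 list sums, 15 RNA class shares and 16 isoform shares also moved, and spike-in totals split the genes 2-fold apart into 393 higher in animal 2 and 152 in animal 1. Genes detected numbered 8244 at a TPM of at least 5. The coefficient of variation was 0.0862 as DESeq2's gene-wise median, an estimator that gave 0.111 on data simulated with 0.2. Genes 2-fold apart numbered 735 at a mean count of 10, 232 at 200, 1316 at 1.5-fold and 140 at 3-fold. The steroidogenesis core summed to 23495 TPM without mitochondrial genes and spike-ins, 64461 over nuclear protein-coding genes and 36321 in the second quantification, where Rn7s1 and Rn7s2 held 0.000502% of TPM. The mitochondrial share was 15.8% of TPM, and in the second quantification 17.6% of counts and 28.5% of TPM. The nuclear protein-coding share was 30.2% of TPM, and in the second quantification 71.9% of counts and 60.1% of TPM. Genes apart between the quantifications numbered 4288 with a pseudocount of 0.1 and 797 after centring. Without length correction, log2 ratios were 4.75 for Cyp11b1 over Cyp11b2, 0.10 for Cyp21a1 over Cyp11b1, 0.77 for Dbh over Pnmt (opposite sign), -0.29 for Dbh over Th and -0.41 for Mc2r over Mrap, by construction, since the transcripts differ in length. In the second quantification they were 3.21 for Cyp11b1 over Cyp11b2, 5.46 for Agtr1a over Agtr1b and -1.05 for Dbh over Th; the cause was not tested. At this depth 1 of 10 T cell genes and 3 of 9 kidney genes reached a mean count of 10, so differences in the others were not assessed.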

Other observations

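Of the tests in this part, those of scaling, of the amount of cortex and of the short RNAs were chosen after the results were seen, while those of the other Akr1c genes, the second fat list and the muscle list were written before their values were seen. With 1 group, no biological explanation was tested.

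Several members of the fixed lists that the naming rule did not take also differed between the gland samples, and those in this paragraph were chosen after their values were seen. The nuclear RNA Neat1 had 56.8 TPM in animal 1 and 234 in animal 2, and Malat1 had 2373 and 4629 TPM. The imprinted RNA H19 had 4.89 and 0.85 TPM. Zbtb16 and Fkbp5, both induced by glucocorticoids, had 5.27 and 23.4 TPM and 16.0 and 33.6 TPM, and the clock gene Per2 had 7.76 and 20.1 TPM. A list of 13 heat shock chaperones, drawn up after Hspa1a and Hspa1b were seen and including both, had a median log2 ratio of 0.45 (percentile 99.95), with 11 of 13 members higher in animal 2 (13 of 13 with spike-in scaling), among them Bag3 (45.2 and 99.5 TPM) and Hspa8 (822 and 1191 TPM). Of the 11 other members, 9 were higher in animal 2 and the median was 0.44.

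X-zone genes had a list median of 3.10, all 3 members being higher in animal 2. Scaling between the libraries is argued against, since the lowest log2 ratio of Akr1c18 over all scalings and both quantifications was 3.09. Reads shared with related genes are too, since the summed counts of all 8 Akr1c genes had a log2 ratio of 3.04 and Akr1c18 held 95.5% and 99.3% of them. A larger amount of cortex in the sample of animal 2 is argued against as the full account by the steroidogenesis core. Its median was -0.15, its mean 0.24 and its highest member 1.44, while Akr1c18 stood at 3.10. A difference between the animals in the extent or activity of the X-zone stays open as a hypothesis, as may a difference in how much of the inner cortex was sampled, and both rest on 2 glands.

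Adipocyte and skeletal muscle genes were higher in animal 1, and a candidate explanation is tissue from around the gland in that sample. A second list of 15 fat genes, with no member in another list, had a median of -0.41 (-0.19 with spike-in scaling), below all random lists, with 12 of 15 members higher in animal 1 (11 with spike-in scaling), led by Car3 (489 and 339 TPM) and Cox8b (360 and 307 TPM). A list of 20 skeletal muscle genes, again with none in another list, had a median of -4.47, below all random lists, with 20 of 20 higher in animal 1, those with the highest TPM in animal 1 being Mb (22.3 and 1.42 TPM), Tnni2 (21.9 and 0.25 TPM) and Pygm (20.3 and 16.6 TPM). Both lists were drawn up after other fat and muscle genes had been seen to be higher in animal 1. Genes of the same tissue vary together, so the lists show how far the pattern extends and are not independent support. Scaling does not account for the fat genes, since the first fat list's highest median over all scalings and both quantifications was -0.41, nor does a trend with gene length and GC content, weighed and set aside after its value of -0.59 was seen. How many of these genes the gland itself expresses was not measured, and the fat genes were abundant in both animals, so a difference in the gland's own cells stays open for them.

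Short RNAs were low in the second transcript table, where the median difference between length and effective length was 328 bases in animal 1 and 323 in animal 2, against 99 in the first. Among genes of at least 10 TPM, 85.1% of 194 under 330 bases were at least 2-fold lower there, against 1.31% of 8231 longer ones, which is consistent with targets shorter than the fragments receiving few counts. Reads divided between identical copies do not account for it, since 82.8% of the 169 short genes with a sequence of their own were also lower, although all 25 short genes and 50% of 18 longer genes with identical copies were lower too, so copies may add to it. Which of the 2 tables lies closer to the true amount of 7SL or other short RNA stays open.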
